A study of Triticum aestivum with 4 samples.

How the data were processed

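The series measured gene expression in leaves of bread wheat (Triticum aestivum) with 4 single-colour arrays, 1 for each combination of 2 varieties, MISR 1 and GEMMZA 7, with infection by leaf rust or without it. Per the labels' protocols, seedlings were grown in a greenhouse, spores of the leaf rust fungus Puccinia triticina were applied, total RNA was extracted with Trizol, and 200 ng was labelled with Cy3 using Agilent's Quick Amp kit. All 4 samples were hybridised in the chambers of 1 slide, so slide is not a batch here.

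The groups came from the sample titles, which match the source names, the descriptions and the series' design text. The labels contradict themselves on 2 points. The inoculant characteristic of every sample says the opposite of its title: it names the rust for the arrays titled non-infected and none for those titled infected. The treatment protocol says that seedlings were 2 weeks old when inoculated, whereas the descriptions of the infected samples put sampling 1 week after infection of younger plantlets, at the 2 weeks of age that all samples carry. The titles were followed, and every infection difference would change sign under the inoculant characteristic.

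Per the file headers, the authors' scanner files hold spot intensities made with Agilent Feature Extraction 9.5.1.1, which subtracted background and corrected spatial trends within each array but did not scale arrays to each other, together with flags of the software for spots well above background, saturated or outlying. The deposited value table of the series is on a log2 scale. Set against the scanner values, differences between its columns equalled those of log2 processed intensity plus 1 constant per array, with a slope of 1.00, and each probe was centred on its median over the 4 arrays. Its column medians were -0.16 for MISR 1 non-infected, -0.00075 for GEMMZA 7 non-infected, 0.26 for MISR 1 infected and -0.014 for GEMMZA 7 infected. The constants lay within 0.01 of the differences between the arrays' 75th percentiles, and the table's scale, centring and direction are therefore known.

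Each array had 45220 spots, 43803 of them outside the controls, for 43603 probes. Control spots and spots with an outlier flag (8 to 13 per array) were left out, log2 processed intensity was reduced by the array's 75th percentile, and the spots of a probe were averaged. A probe not well above background on one side of a comparison has only a bound there. Its difference was computed against the higher of its own signal and the lowest signal among probes well above background on that array, is written "at least", and was set to no difference where the bound was under 1. A mean over both varieties or both infection states is likewise a bound where any array on its lower side was dim, whereas the model used the measured values. Named probes were ranked on bounds within a variety and on measured values elsewhere.

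With 1 array per group, a difference within a variety or between varieties in a single infection state has no replicate check, and no p-value is given for it. These comparisons are counts of probes at least 2-fold apart, over probes well above background on at least 1 of the compared arrays. The only test was an additive model of variety and infection over the 4 arrays, fitted with limma 3.58.1 (lmFit, eBayes) in R 4.3.3 to the 42342 probes well above background on at least 2 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. Nothing in the labels says that the arrays come from more than 1 pool of plants per group, so this test measures the disagreement between the varieties' responses rather than a spread between replicate plants. It has 1 residual degree of freedom per probe. The estimated prior degrees of freedom were infinite, so that all probes shared 1 standard deviation of 0.596 on the log2 scale, and a call amounts to a fixed threshold: the smallest called absolute difference was 1.68 for infection and 2.07 for variety. Its very small p-values rest on that shared value.

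Gene names are those of the array design. Of the probes, 11811 are described as unknown, 10286 name a product, and 15474 carry the name of a best database hit, often in another organism and with a stated percentage of the hit's length covered. Such names are written here as best hits. A hit that covers a few percent of a distant organism's protein says little about the gene. Of 2371 gene names that are symbols or LOC numbers, 984 were found in the RefSeq gene table, and no accession was. Genome coordinates were not used here.

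The 27 gene lists, the comparisons, the alternatives and the rule for named probes were fixed before the data were examined. Lists were matched by words in the descriptions, so a probe can be in more than 1 list, as 53 were. A list's median difference was set against 10000 random lists of the same size matched on mean level in 20 bins, and its distance from the random lists' median is called its relative median. The percentile describes these arrays and is not a test. Named probes have a named product and are taken once per description, which ends in the number of a sequence assembly, so that 2 probes of 1 gene can both be named: the 10 highest and 10 lowest called over both varieties, the 6 highest and 6 lowest in each variety, the 5 highest and 5 lowest for variety and for the difference between responses, and 2 per list by absolute mean difference. A named product excludes hypothetical and uncharacterised proteins and clone titles, except in the last part, which takes every member of a list whose text the pattern matched and so includes 2 hits to genome sequence.

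The alternatives were quantile normalization, centring on the median of probes well above background on all 4 arrays, normexp background correction with an offset of 50, 2 other filters on dim probes, the deposited value table, a prior with trend and robust estimation, a model without the other factor, and leaving out each array. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the counts and lists, and matplotlib 3.10.9 for figures. The fit was tested on simulated data for infected against non-infected over both varieties, on 42342 probes with the fitted spread. Of 100 probes changed by 2 on the log2 scale, 39 were recovered, of 100 changed by 4, all 100 were, and 11 unchanged probes were called. The simulated probes all had the same normal spread and no true difference between the varieties' responses, as the model assumes. These figures thus check the code and do not measure the error in these arrays. For the list percentiles, 4 of 100 simulated unshifted lists of 50 probes fell outside the central 95%, and 99 of 100 shifted by 0.5 lay above it. Those probes were simulated as independent and of equal spread, which real lists need not be.

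The number of arrays limits the precision. The 75th percentile of the processed intensity was 1828 for MISR 1 non-infected, 1311 for GEMMZA 7 non-infected, 785 for MISR 1 infected and 1394 for GEMMZA 7 infected, and between 94.8% and 97.4% of probes were well above background. The 50 probes with 5 spots had a median standard deviation between spots of 0.090, 0.086, 0.091 and 0.124 on the log2 scale in the same order, which is technical error within an array only. 1 probe was saturated, on the array of infected MISR 1.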

Results

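Leaves of 2-week-old bread wheat plantlets of the varieties MISR 1 and GEMMZA 7, infected with leaf rust (Puccinia triticina, an obligate fungal parasite of wheat leaves) or non-infected, were compared on 4 single-colour wheat arrays of 43603 probes, 1 array per group (n = 1 throughout). The series set out to find wheat genes that respond to leaf rust. Here "infected" and "non-infected" are the titles of the arrays, which the inoculant characteristic contradicts in all 4 samples. The arrays of the non-infected varieties were the most alike, with a correlation of 0.973 over probes well above background on all 4 arrays. Those of the infected varieties correlated at 0.933, and infected with non-infected at 0.887 in MISR 1 and 0.876 in GEMMZA 7. The array of infected MISR 1 was the dimmest, and its 100 brightest probes held 26.3% of its signal against 14.6% to 17.7% on the other arrays.

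The first question was which probes differed between infected and non-infected leaves over both varieties. Among called probes, chitinases, glucanases and pathogenesis-related proteins were mostly higher, and ribosomal proteins, histones, cyclins and tubulins mostly lower, in infected leaves. Among probes with a plant name, the largest higher values were those of a probe whose best hit is peroxidase 47 (27% covered; at least 175-fold), the beta-1,3-glucanase TaGlb2a, an enzyme that cleaves a glucan of fungal cell walls (mean log2 difference 5.79), a protein kinase (5.60) and a thaumatin-like protein, a class of antifungal pathogenesis-related proteins (at least 43.8-fold). Among the lowest were Meiosis 5, at least 1895-fold lower since it was not well above background on either infected array, the beta-glucosidase TaGlu1a (at least 285-fold lower), a type 1 non-specific lipid transfer protein (-7.49), a xyloglucan endotransglycosylase best hit named XTH-30, an enzyme class that loosens the cell wall (-7.40), and a GDSL-motif lipase (-7.06). Each had the same sign in both varieties, but TaGlu1a was not well above background on the infected GEMMZA 7 array, nor the peroxidase and the thaumatin-like protein on that of non-infected MISR 1.

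By the additive limma model, 1797 probes were called higher and 2280 lower in infected leaves of 42342 tested at an adjusted p under 0.05. Of these, 1647 and 2016 were also at least 2-fold apart in that direction within each variety, and 72 called probes had opposite signs in the varieties. The 20 named probes of this comparison all had an adjusted p of at most 1.87e-17 and a standard error of 0.596, which is the same for every probe. Of 61 probes named over both varieties or from a gene list and called for infection, 44 were called under every alternative that tested them, 10 of these outside the filter for probes well above background on all 4 arrays. The other 17 lost their calls under at least 1 alternative. Among them, TaGlu1a was not called with the trend and robust prior (adjusted p from 2.61e-47 to 0.185 over the alternatives). Calls were fewer without either non-infected array and more without either infected array, from 596 to 3734 higher and from 1090 to 3593 lower.

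Several of the highest named probes carry fungal best hits. The ribosomal protein L10 of Botryotinia and L2 of Sclerotinia, both ascomycete plant pathogens and both covered in full length, were at least 56.3-fold and 23.4-fold higher in infected leaves and not well above background on either non-infected array. A probe with 18% of the Botryotinia elongation factor 1-alpha was higher by 8.03 on the log2 scale in MISR 1 and 6.38 in GEMMZA 7. A hit to Aspergillus oryzae genome sequence was at least 64.0-fold higher. Other extreme probes have hits that cover 3% to 10% of a protein of a distant organism, and their names carry little weight. Among these, probes with hits to a frog keratin (6.63) and a pufferfish protein (6.60) were higher, as was one to wombat apolipoprotein B (at least 56.5-fold), and probes with hits to a bacterial UDP-galactose epimerase (-8.05) and a human Rab-like protein (-7.99) were lower. Further low probes were best hits to a nucleoid DNA-binding-like protein (-7.10), a barley structural protein (-7.09) and a lipid transfer and amylase inhibitor domain protein (-7.08), the last of which differed far more in GEMMZA 7 (-11.70) than in MISR 1 (-2.46).

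**Figure D1:**
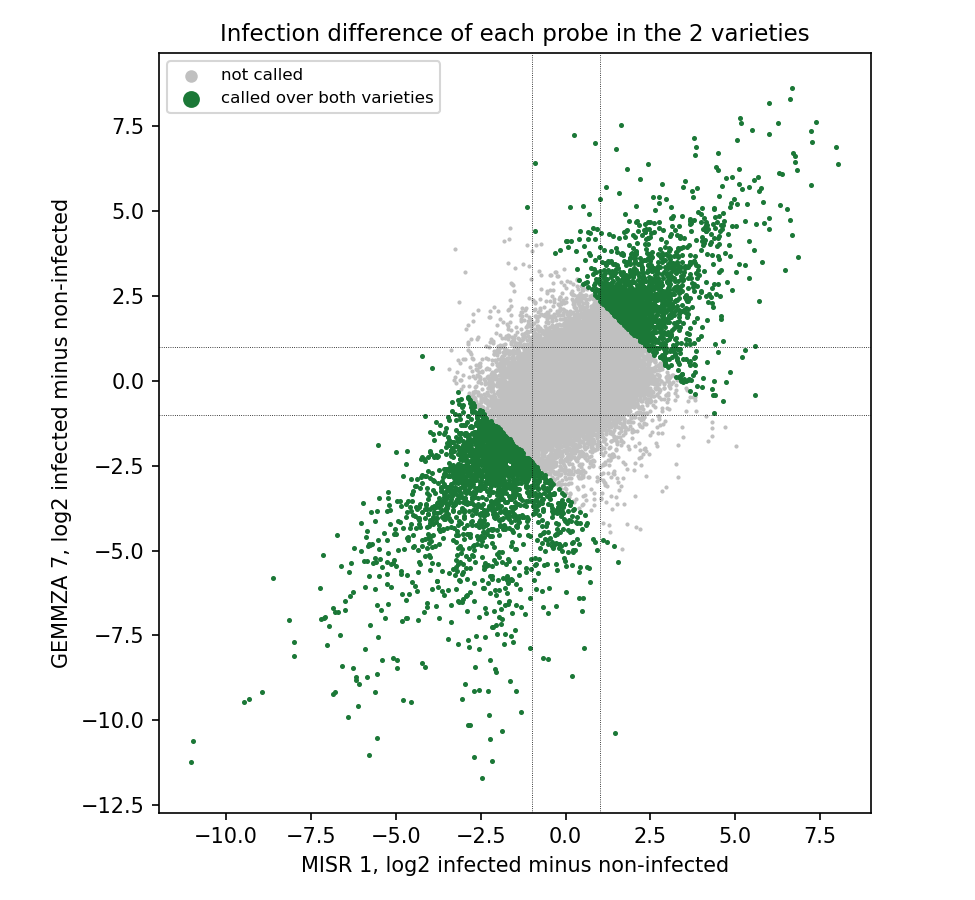
Each point is 1 of 42342 probes, with its log2 difference of infected minus non-infected in MISR 1 on the horizontal axis and in GEMMZA 7 on the vertical axis; dotted lines mark 2-fold, and green points were called over both varieties by the additive model. A call is a threshold on the mean of the 2 differences, so called probes can lie far from the shared diagonal. Of the called probes, 72 have opposite signs in the varieties.

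Lists fixed beforehand were compared with the calls. Of 51 probes for chitinases and beta-1,3-glucanases, which degrade fungal walls, 16 were called higher and 0 lower (18 and 0 adjusted over the list alone). Pathogenesis-related proteins had 12 higher and 1 lower of 46 (13 and 1 adjusted over the list alone), including a second, full-length thaumatin-like protein (at least 18.4-fold), which was not well above background on the non-infected GEMMZA 7 array. Of 67 probes for WRKY and NAC transcription factors, families of stress regulators, 12 were called higher and 1 lower (22 and 2 adjusted over the list alone), led by a full-length wheat WRKY (at least 12.5-fold higher) and another at 3.21. Receptor kinases and resistance proteins had 17 higher and 3 lower of 127 (22 and 4 adjusted over the list alone), with a wheat resistance-related receptor-like kinase at 4.70 and a barley NBS-LRR best hit at least 13.0-fold higher. Senescence and protein breakdown had 13 higher and 1 lower of 87 (16 and 1 adjusted over the list alone), with a cysteine proteinase at 3.38, while the wheat senescence-associated protein SAP was the lower one (-3.82). Glutathione transferases and detoxification had 10 higher and 4 lower of 131 (10 and 4 adjusted over the list alone). Its 2 most extreme members were lower, a glutathione transferase domain protein (-3.38) and a 5% hit to a bacterial iron transporter (at least 10.9-fold lower). The median of each of these 6 lists lay above the central 95% of matched random lists in both varieties, except that of chitinases and glucanases in GEMMZA 7 (percentile 94.6).

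Lists on the lower side by their calls were led by ribosomal proteins, with 113 called lower and 15 higher of 385 (164 and 24 adjusted over the list alone). All 15 higher members had a fungal best hit, and of the 342 members with another best hit 0 were called higher and 113 lower. Histones, cyclins and tubulins, which mark dividing cells, had 18 lower and 1 higher of 115 (20 and 1 adjusted over the list alone), with a best hit to the mitotic cyclin B2-2 at -5.99 and a short hit to alpha-tubulin at -5.17. Heat shock proteins had 22 lower and 0 higher of 140 (29 and 0 adjusted over the list alone), including 2 mitochondrial chaperonin best hits, CPN60-1 (-3.61) and CPN60-2 (-3.56). The medians of these 3 lists lay below the central 95% of matched random lists in both varieties. Lipid transfer, wax and epidermis had 15 lower and 4 higher of 74 (15 and 6 adjusted over the list alone). But the median of this list lay above the central 95% of matched random lists in MISR 1 (relative median 0.36). In the other variety it lay below (-0.44). Proteinase inhibitors had 5 lower and 0 higher of 50 (5 and 0 adjusted over the list alone), a protease inhibitor-like protein at -4.66 and a Bowman-Birk trypsin inhibitor at -4.28. Defensins and thionins had 3 lower and 0 higher of 17 (3 and 0 adjusted over the list alone), with 2 wheat defensins at -3.72 and -3.12. Chlorophyll and carotenoid synthesis had 3 lower and 0 higher of 25 (3 and 0 adjusted over the list alone), among them glutamate-1-semialdehyde aminomutase (-1.88), which was not called under quantile normalization or without either non-infected array. In MISR 1 the medians of proteinase inhibitors, defensins and chlorophyll synthesis lay inside the central 95% (relative medians 0.01, 0.05 and -0.39). In the other variety they lay below it (-0.35, -0.42 and -0.46).

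Other lists had members called in both directions or few calls, given here as higher and lower. Peroxidases and germin-like oxidases had 8 and 7 of 91 (8 and 9 adjusted over the list alone). Phenylpropanoid and lignin enzymes had 5 and 4 of 72 (5 and 4 adjusted over the list alone), with the flavonoid enzymes flavanone 3-hydroxylase (4.58) and chalcone synthase (4.55) higher. Jasmonate and oxylipin enzymes had 4 and 5 of 30 (4 and 5 adjusted over the list alone), and 2 probes for allene oxide synthase, an enzyme of jasmonate synthesis, were lower by mean log2 differences of -3.34 for the barley best hit and -3.27 for TaAOS. Cytochromes P450 had 4 and 5 of 49 (4 and 5 adjusted over the list alone), with P450 74A4 at -4.21 and a P450 monooxygenase at 2.43. Ethylene synthesis and response had 1 and 0 of 30 (1 and 0 adjusted over the list alone), the ethylene-forming aminocyclopropane carboxylate oxidase (at least 9.76-fold higher), which limma no longer called with no variety term or without GEMMZA 7 infected (adjusted p from 3.81e-07 to 0.0989 over the alternatives), while ethylene-responsive element binding protein 2 was not called (1.41, adjusted p = 0.130). Sugar cleavage, fructans and transport had 4 and 4 of 83 (4 and 4 adjusted over the list alone), with a monosaccharide transporter 4 best hit at 4.69 and a fructosyltransferase-like protein at -4.91. Calvin cycle and photorespiration had 2 and 4 of 54 (2 and 4 adjusted over the list alone), with fructose-1,6-bisphosphatase 2 at 2.77. The Rubisco subunit binding protein alpha (-3.71) entered this list through the word Rubisco and is not itself an enzyme of the cycle. Light harvesting and photosystems had 3 and 6 of 104 (3 and 6 adjusted over the list alone). Dehydrins, LEA and cold-regulated proteins had 2 and 5 of 105 (1 and 5 adjusted over the list alone), a low temperature induced protein at -4.70 and a cold acclimation protein at 3.43. Of 47 probes for antioxidant enzymes, limma called 0 higher and 0 lower, also adjusted over the list alone, with monodehydroascorbate reductase at 1.67 (adjusted p = 0.0519) and thylakoid ascorbate peroxidase at -1.54 (adjusted p = 0.0849).

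Markers of other material were measured too. The list of fungal words had 27 and 10 of 399 (27 and 10 adjusted over the list alone). But the descriptions of 207 of its members name a cDNA library, such as one from Fusarium-infected spikes, whose title can supply the fungal word. The second example taken from it, a 7% hit to Aspergillus niger sequence, was at least 15.9-fold lower and not well above background on the infected GEMMZA 7 array. Seed storage proteins had 1 and 10 of 129 (1 and 9 adjusted over the list alone). The lower ones include lipid transfer and amylase inhibitor domain proteins, which the lipid transfer list holds too. The iron and nicotianamine list of roots had 0 and 1 of 23 (0 and 1 adjusted over the list alone). The called one was a nicotianamine synthase 2 best hit at -2.11, lost under 4 alternatives, and nicotianamine synthase 3 stood at 1.39 (limma adjusted p = 0.138). Widely used reference genes had 3 and 5 of 92 (3 and 5 adjusted over the list alone), with an actin-1 best hit at -3.46. The higher ones include the elongation factor 1-alpha fragment with a Botryotinia best hit (7.20), so not every member need be a wheat gene.

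**Figure D2:**
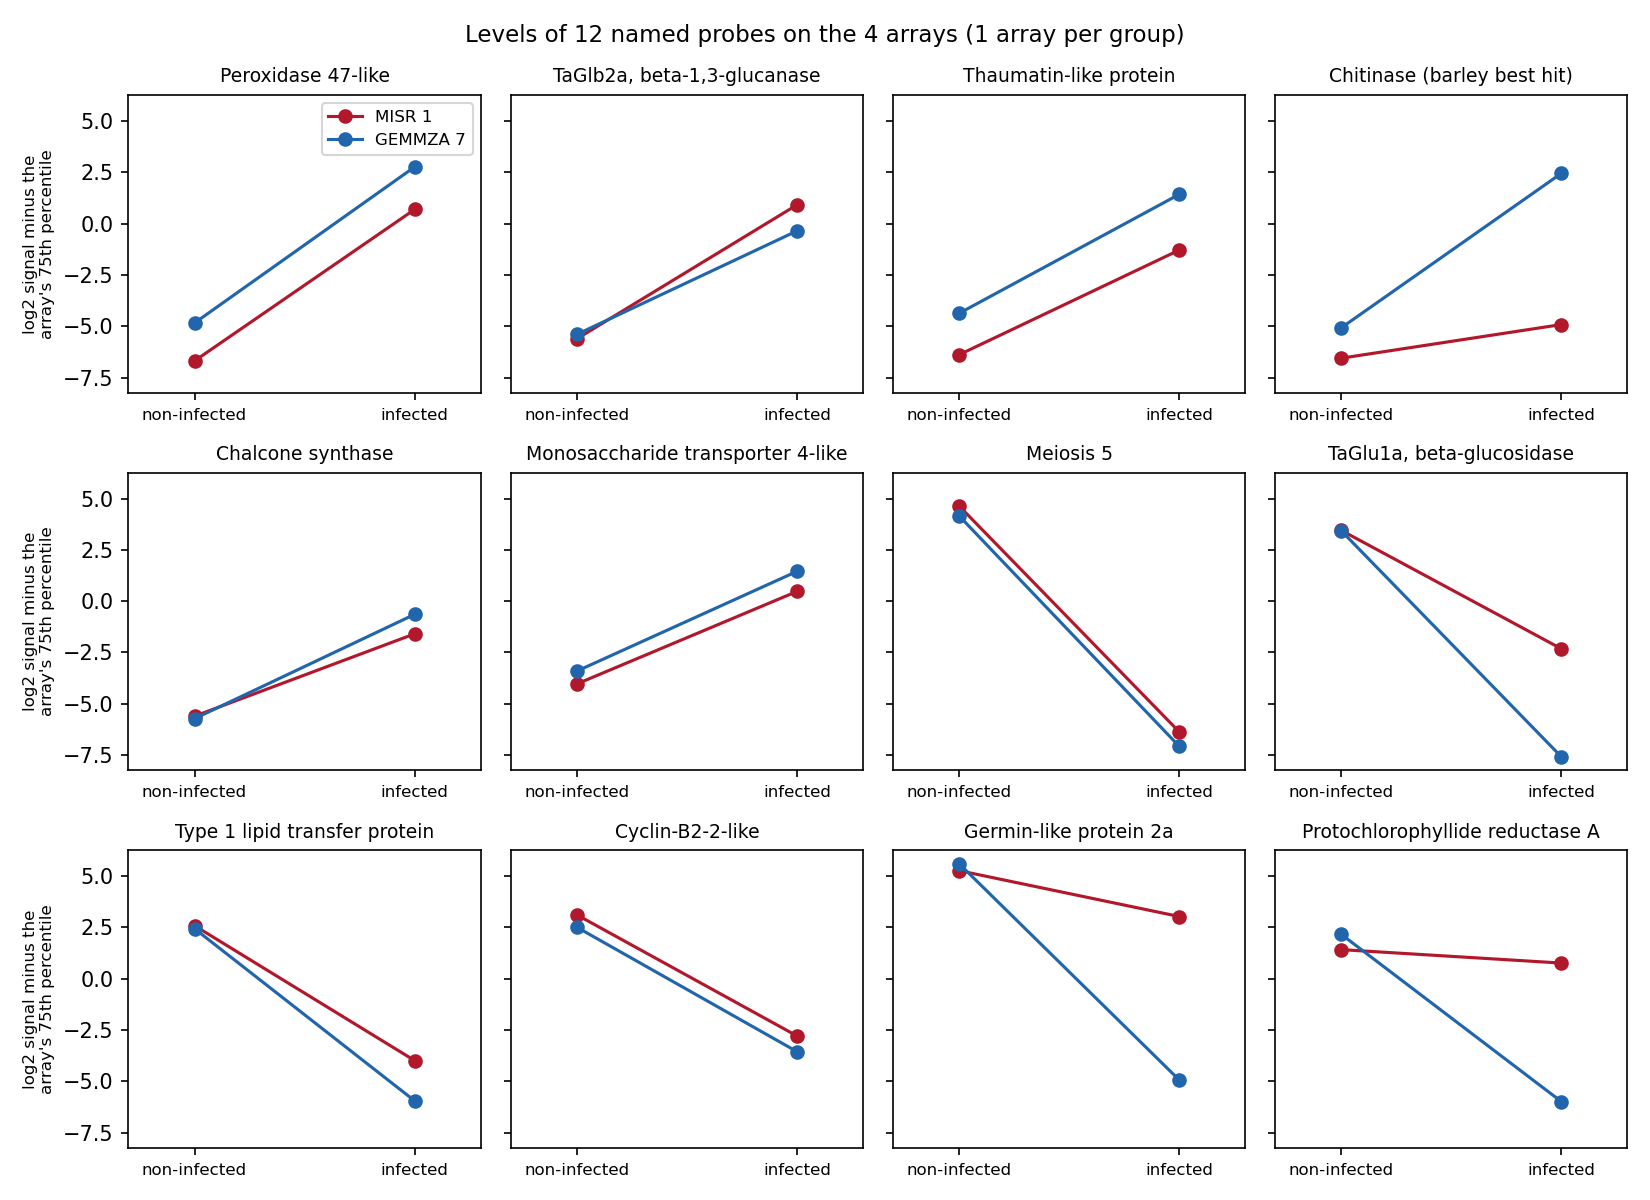
Levels of 12 named probes on the 4 arrays, as log2 signal minus the array's 75th percentile on a shared vertical axis; each point is 1 array, red for MISR 1 and blue for GEMMZA 7, and lines join the arrays of a variety. Peroxidase 47 differs by similar amounts in both varieties, whereas germin-like protein 2a differs by -2.24 in MISR 1 and -10.55 in GEMMZA 7.

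Within MISR 1, 12126 probes were at least 2-fold higher and 5261 at least 2-fold lower in infected leaves of 42425 compared. Ranked with bounds for dim probes, the highest named probes were the elongation factor 1-alpha fragment (8.03), the peroxidase 47 best hit (at least 157-fold), the pufferfish hit (6.74), TaGlb2a (6.53), the frog keratin hit (5.99) and a wheat kinase R-like protein (5.78). The lowest were Meiosis 5 (at least 1486-fold), the bacterial epimerase hit (-8.01), XTH-30 (-7.03), the barley structural protein (-6.95), the Rab-like hit (-6.80) and a second GDSL-motif lipase (-6.69). The median over all probes in this comparison was 0.50, against -0.0037 in GEMMZA 7. Higher probes made up 69.7% of those 2-fold apart, and this share was 47.1% (5958 higher, 6694 lower) under quantile normalization and 50.1% (7181 and 7160) with median centring, scalings that themselves tend to balance the 2 directions. Whether there is an excess, and how large it is, thus depends on the scaling.

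Within GEMMZA 7, 5212 probes were at least 2-fold higher and 5748 at least 2-fold lower of 42667. The larger side changed under quantile normalization (5564 higher, 5172 lower) and not with median centring (5081 and 5863). By the same ranking, the highest were the peroxidase 47 best hit (7.61), a chitinase with a barley best hit (7.53), the frog keratin hit (7.26), the protein kinase (6.72), the pufferfish hit (6.45) and the elongation factor fragment (6.38). The lowest were 3 probes for lipid transfer and amylase inhibitor domain proteins (-11.70, -11.09 and -10.15), the first and last of which carry the same sequence identifier, Meiosis 5 (at least 2418-fold), germin-like protein 2a (-10.55) and TaGlu1a (at least 1486-fold). Both members named from the light harvesting list, best hits to the chlorophyll a-b binding proteins 91R and 3C, were lower in this variety by -6.68 and -6.63 and stood at -0.66 and -0.27 in MISR 1. The chlorophyll synthesis enzyme protochlorophyllide reductase A was at -8.16 and -0.66.

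The responses of the varieties overlapped. Of probes compared in both, 2918 were 2-fold higher in both, where 1470 would be shared by independent lists of these sizes, and 2974 were lower in both, where 709 would be. Another 288 were higher in MISR 1 and lower in GEMMZA 7, and 124 the reverse. Across 42342 probes, which are not independent replicates, the responses correlated with r = 0.588 and rho = 0.426.

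The gene lists differed in how the varieties compared. Relative to matched random lists, the median of ribosomal proteins was -1.54 in MISR 1 and -0.75 in GEMMZA 7, and that of histones, cyclins and tubulins -0.87 and -0.41. WRKY and NAC factors stood at 0.81 and 0.43, pathogenesis-related proteins at 0.83 and 0.33, and senescence and protein breakdown at 0.58 and 0.41. Chitinases and glucanases stood at 0.77 and 0.20, receptor kinases at 0.43 and 0.29, glutathione transferases at 0.44 and 0.27, and heat shock proteins at -0.30 and -0.46. Calvin cycle and photorespiration had 0.69 in MISR 1, which turned to -0.043 under quantile normalization, and 0.01 in GEMMZA 7. Dehydrins stood at 0.28 and -0.08, sugar cleavage and transport at 0.34 and 0.05, antioxidant enzymes at 0.02 and -0.40, and proteinase inhibitors at 0.01 and -0.35. Peroxidases stood at 0.19 and -0.19, jasmonate enzymes at 0.10 and -0.36, defensins at 0.05 and -0.42, chlorophyll synthesis at -0.39 and -0.46, ethylene at 0.26 and 0.19, and cytochromes P450 at 0.13 and -0.11. The root list stood at 0.10 and 0.44, the fungal list at 0.25 and 0.01, and reference genes at -0.06 and -0.13. Phenylpropanoid enzymes, light harvesting, lipid transfer and seed storage proteins lay on opposite sides in the 2 varieties.

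**Figure D3:**
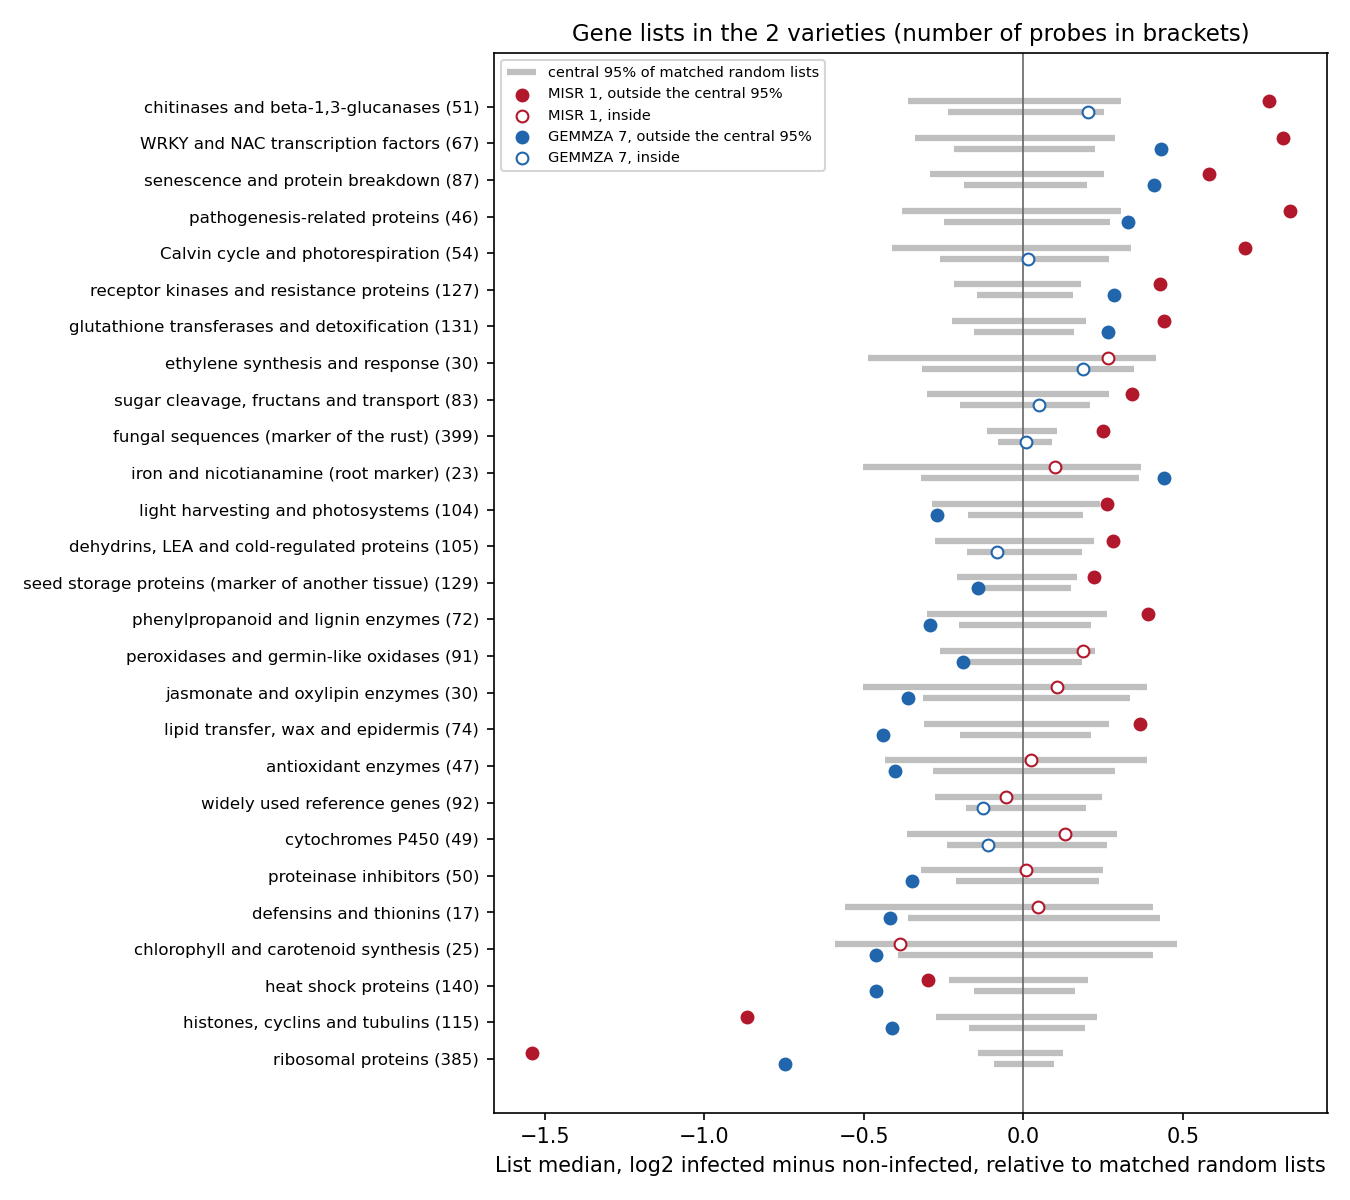
Median log2 difference of infected minus non-infected of each of the 27 gene lists, relative to 10000 random lists matched on mean level, in MISR 1 (red) and GEMMZA 7 (blue); grey bars span the central 95% of the random lists, and filled points lie outside it. Ribosomal proteins are lowest in both varieties (-1.54 and -0.75), and WRKY and NAC factors and pathogenesis-related proteins are above their bars in both.

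The second question was how the varieties differed. MISR 1 was higher than GEMMZA 7 over both infection states for a probe with a chloroplast ribosomal protein L28 best hit (at least 194-fold), the wheat Hessian fly response gene Hfr-1, a lectin gene (mean log2 difference 4.69), the senescence-associated protein SAP (4.59), a lipid transfer and amylase inhibitor domain protein (4.27) and germin-like protein 2a (3.81). GEMMZA 7 was higher for short bacterial hits to a ribonuclease III (at least 104-fold), a phospholipase C (-6.52), a DNA polymerase subunit (at least 53.0-fold) and an HPr kinase (at least 39.9-fold), and for an elongation factor EF-2 best hit (at least 22.0-fold). The ribonuclease, polymerase and EF-2 probes were not well above background on either MISR 1 array, the kinase probe on that of non-infected MISR 1, and the L28 probe on that of non-infected GEMMZA 7. The L28, ribonuclease, phospholipase, polymerase, EF-2 and kinase probes differed in the same direction by at least 17.5-fold in both infection states. The lipid transfer and germin-like probes differed by -0.35 and -0.34 in non-infected leaves and by 8.89 and 7.97 in infected leaves, so their variety call comes from the infected arrays.

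By the limma model, 283 probes were called higher in MISR 1 and 145 in GEMMZA 7. Only 133 of these 428 were called under quantile normalization, 2 without the infection term, and 0 without either MISR 1 array. In non-infected leaves, 1360 probes were at least 2-fold higher in MISR 1 and 1714 in GEMMZA 7 of 41986. The direction of this split turned under quantile normalization (1641 and 956) and with median centring (1592 and 1387). In infected leaves the counts were 6069 and 2383 of 42727, a split of 71.8% higher. That share was 45.3% (3258 and 3941) under quantile normalization and 51.8% (4008 and 3733) with median centring. The variety difference of non-infected leaves correlated with that of infected leaves across probes at r = -0.046 and rho = -0.254.

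The third question was which responses to infection differed between the varieties, a difference that 4 arrays cannot test. The named probes with the most positive difference of responses, MISR 1 minus GEMMZA 7, were 2 lipid transfer and amylase inhibitor domain proteins, germin-like protein 2a, a proline-rich protein (-1.46 in MISR 1 and -9.14 in GEMMZA 7) and a best hit to the chloroplast ribosomal protein S17 (0.18 and -8.70). All 5 were far lower in infected than in non-infected GEMMZA 7. In MISR 1 the S17 probe was not lower, and the others were lower by less. At the other end, the chitinase with a barley best hit was at least 3.12-fold higher in MISR 1 and 185-fold higher in GEMMZA 7. Short hits to frizzled-2 (-1.14 and 5.12), ribosomal protein S27a (-1.81 and 4.12), malic enzyme (-3.15 and 2.33) and a glycine-rich protein (-0.91 and 4.42) were lower in infected MISR 1 and higher in infected GEMMZA 7. Over all probes, 11820 had a response larger by at least 2-fold in MISR 1 and 3965 a smaller one, with a median difference of 0.40. With that median removed the counts were 6526 and 7421.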

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

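The tests that weigh explanations in this part were chosen only after the results were seen, whereas the gene lists and the rule for named probes were planned.

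Outside the planned comparisons, 30 probes of the wheat array have a best hit to a Botryotinia or Sclerotinia protein (Leotiomycetes) over at least 50% of its length, of which 14 were over 4-fold higher in infected leaves in both varieties, and limma called 15 higher and 0 lower. Of 54 with such a hit to other ascomycetes, 9 were called higher and 0 lower, but their relative median was inside the central 95% of random lists in GEMMZA 7 (0.12) and above it in MISR 1 (0.37). Under quantile normalization 11 of the 30 were over 4-fold higher in both. The 14 and the 11 were counted on measured values rather than bounds. Of the 30, 23 were well above background on the non-infected MISR 1 array and 25 on the non-infected GEMMZA 7 array. Some of these folds may thus rest on dim signals. Relative to matched random lists the median of the 30 was 1.33 in GEMMZA 7 under quantile normalization, above all 10000, and those arrays were about equally bright. Hits to these genera were already among the highest named probes, so the set was picked from these same arrays. Its place above random lists is therefore no independent support, and it cannot decide whether dimness or scaling is the cause. The 43 ribosomal probes with fungal best hits lay 2.51 above the 342 others in their median over both varieties. The median of the former was higher and that of the latter lower in infected leaves. Cross-hybridising wheat transcripts of the same proteins would move both in the same direction. But the split was made after fungal hits were seen among the highest probes, so it is no independent test of cross-hybridisation. RNA of a fungus in the infected leaves may account for the Leotiomycete hits, a direction that goes with the titles rather than the inoculant characteristic, but whether it is the inoculated rust, a Basidiomycete, stays open, because only 1 probe has a Basidiomycete best hit of that length (0.69 in MISR 1 and -0.17 in GEMMZA 7).

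Wheat ribosomal probes, those without a fungal best hit, were lower in infected leaves, with 113 of 342 called lower by limma and 0 higher. Array scaling is argued against only as a shift shared by probes of the same level, which cancels in a relative median. Their relative median in GEMMZA 7 was -0.92 under quantile normalization, below all 10000 matched random lists. The planned ribosomal list, which holds these probes, already lay at -0.75 there under the main scaling, so a low value was foreseeable. The dim array of infected MISR 1 enters no GEMMZA 7 difference. The relative median of -1.05 in GEMMZA 7 thus argues against its dimness as the cause, for that variety only. Less growing tissue in the leaves sampled as infected, through age, leaf position or slowed growth, cannot be told apart from a direct effect of infection. Probes for expansins, xyloglucan endotransglycosylases and cellulose synthases were at -0.19 in MISR 1, inside the central 95% of random lists, and at -1.24 in GEMMZA 7, below all of them, and the labels conflict on age at infection.

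The third pattern is the excess of higher probes in infected MISR 1, 69.7% of those 2-fold apart under the main scaling. This share was 47.1% under quantile normalization and 50.1% with median centring, scalings that themselves tend to balance the 2 directions. Among 4 equal classes of probes by mean level, the median difference of the dimmest lay 1.08 above that of the brightest in MISR 1 and 0.031 above it in GEMMZA 7, as a compressed dim array would give. The E1A control probes, designed against an adenoviral sequence, were 1.37 higher in infected than in non-infected MISR 1 after scaling, and at -0.11 in GEMMZA 7. Before scaling their median signal was 109 in non-infected and 121 in infected MISR 1. Most of the 1.37 thus comes from the lower 75th percentile of the infected array, 785 against 1828. Signal that does not come from wheat transcripts stays open, since wheat probes of the same level had a median of 0.84 in MISR 1 and the E1A value lay inside their central 95%. A wider response of MISR 1 stays open: the share of higher probes was 39.6% in the brightest class and 90.5% in the dimmest, where compression may act too, and 1 array per group cannot separate a response from its array.

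Of the lists, 4 lay outside the central 95% of random lists on opposite sides in the 2 varieties, a difference that was not tested. Phenylpropanoid and lignin enzymes had a relative median of 0.39 in MISR 1 and -0.29 in GEMMZA 7. Light harvesting and photosystems stood at 0.26 and -0.27, lipid transfer, wax and epidermis at 0.36 and -0.44, and seed storage proteins at 0.22 and -0.14. The last 2 lists share probes, since the lipid transfer and amylase inhibitor domain proteins match the words of both. Among the named probes, 4 differed by at least 2-fold in opposite directions, also untested: Hfr-1 by 2.32 and -2.01, and the short hits to frizzled-2 by -1.14 and 5.12, ribosomal protein S27a by -1.81 and 4.12 and malic enzyme by -3.15 and 2.33.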

How the results depend on the processing

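The alternatives were fixed before the data were examined, except 2 for the list medians, added after seeing the data: list words matched without cDNA library titles, and ribosomal proteins without fungal best hits. No paired analysis was possible because the labels give no replicate numbers and each group has 1 array, but the variety term compares arrays within each variety, and without it 2941 probes were called for infection rather than 4077. When an array is left out, its arm keeps 1 array, the model drops the other factor, and that lone array is assumed to vary like the others. Variety and infection are then mixed in each value, so such fits are not a like-for-like check of either effect. The cause of the changes below was not tested except where it follows from the setting. Signal over background limited few probes, and the filters on dim probes moved no count by over 1.5 times.

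Of the calls for infection, 3485 of 4077 were shared with quantile normalization, 3344 with normexp, 3619 with the trend and robust prior and 2828 with no variety term. Without 1 array, the counts ran from 596 to 3734 higher and from 1090 to 3593 lower, the lowest without MISR 1 non-infected. Of the 61 probes named over both varieties or from a gene list and called for infection, 44 were called under every alternative that tested them, 10 of these outside the filter for all 4 arrays. Of the 17 others, germin-like protein 2a, the lipid transfer and amylase inhibitor domain proteins, protochlorophyllide reductase A and the chlorophyll a-b binding proteins lost their calls with the robust prior and with no variety term, as did the low temperature induced protein. With no variety term the chitinase, SAP, the NBS-LRR protein, the second thaumatin-like protein and aminocyclopropane carboxylate oxidase lost theirs. Nicotianamine synthase 2 and the aminomutase lost theirs without either non-infected array, the P450 monooxygenase and fructose-1,6-bisphosphatase 2 without MISR 1 non-infected, and TaGlu1a with the robust prior. For germin-like protein 2a the adjusted p ran from 7.41e-28 to 0.700 over the alternatives.

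The calls between the varieties depended on the setting. Higher and lower counts were 51 and 82 under quantile normalization, 174 and 81 with normexp, and 1 and 1 with no infection term, where 454 probes had an unadjusted p under 0.05. Without 1 array they ran from 0 to 323 higher and from 0 to 91 lower, with 0 by limma without MISR 1 non-infected (1002 with an unadjusted p under 0.05) and without MISR 1 infected (499). None of the 10 probes named for variety was called under every alternative that tested it. Without GEMMZA 7 infected, the differences of the lipid transfer and amylase inhibitor domain protein and of germin-like protein 2a reversed to -1.58 and -1.46, with 10.12 and 9.09 the highest without 1 array. The reversed values set both MISR 1 arrays against GEMMZA 7 non-infected alone, and so include part of the infection difference of MISR 1. Between the non-infected arrays the varieties differed by -0.35 and -0.34.

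Counts of 2-fold differences moved with the scaling. Quantile normalization gave 5958 higher in infected MISR 1, 956 lower in MISR 1 than GEMMZA 7 non-infected, 3258 and 3941 between the infected varieties, and 5751 larger and 6083 smaller responses in MISR 1. Median centring gave 7181 higher in infected MISR 1, 4008 and 3733 between the infected varieties, and 6002 smaller responses. Normexp, whose offset shrinks dim probes, gave 756 and 960 between the non-infected varieties, 3751 and 1518 between the infected varieties, and 2631 smaller responses. The correlation of responses ran from 0.575 to 0.598. Of 272 list medians under alternatives, 251 kept their side of the central 95%, 13 came inside the central 95%, 7 went outside it, and 1 reversed: Calvin cycle and photorespiration in MISR 1, at -0.043 under quantile normalization.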

Other observations

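The groups of probes in this part were chosen after the results were seen. Of 9 further groups taken by words in the product names, without fungal best hits, expansins, xyloglucan endotransglycosylases and cellulose synthases, which build or loosen growing cell walls, had 15 called lower and 1 higher of 62 by limma. Among them an expansin-A5 best hit was at -4.83, with -3.18 in MISR 1 and -6.49 in GEMMZA 7. F-box, RING and ubiquitin proteins, which mark proteins for breakdown, had 7 higher and 2 lower of 225 and a relative median of 0.18 in MISR 1 and 0.35 in GEMMZA 7, both above the central 95% of random lists. A wheat RING-H2 zinc finger gene was higher by 4.31 and 2.29 and a polyubiquitin best hit by 1.78 and 4.42. Aquaporins, the water channels, had 3 higher and 2 lower of 47, with the tonoplast channel TIP2;3 at -2.87 and TIP4-2 at 2.28. Their relative median was 0.71 in MISR 1 and -0.23 in GEMMZA 7, the second inside the central 95%.

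Enzymes of the tryptophan and shikimate pathway had 2 lower and 0 higher of 25, an anthranilate phosphoribosyltransferase best hit at -4.16 and anthranilate synthase alpha 1 at -3.25, both steps of tryptophan synthesis. Transporters of amino acids, peptides, nitrate and ammonium had 3 higher and 0 lower of 24. The wheat nitrate transporter NRT1.1 was at 5.15 in GEMMZA 7 and 0.51 in MISR 1, and a peptide transporter best hit at 2.72 in GEMMZA 7 and 1.30 in MISR 1. Protein folding in the endoplasmic reticulum had 2 higher and 1 lower of 48, with an endoplasmin best hit at 4.10 in GEMMZA 7 and 0.17 in MISR 1 and a protein disulfide isomerase best hit at a mean of -1.93. The relative median over both varieties was -0.34, below the central 95% of random lists. The word BiP was matched in any case and inside longer words, so the 48 may hold other proteins. RNA polymerases, helicases and nucleolar proteins had 1 higher and 4 lower of 120, aminotransferases 3 and 0 of 21, and calmodulins, calcium-dependent kinases, annexins and calreticulins 0 and 1 of 70.

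Among the ribosomal probes without fungal best hits, 56 of 170 described as 40S or 60S were called lower, with relative medians of -1.81 in MISR 1 and -0.97 in GEMMZA 7. Of 40 described as 30S, 50S or chloroplast, 18 were called lower, with -1.29 in MISR 1 and -1.71 in GEMMZA 7. Probes with a best hit of at least 50% to other ascomycetes numbered 54, of which 9 were called higher and 0 lower. Their relative median was 0.37 in MISR 1 and 0.12 in GEMMZA 7, the second inside the central 95%.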
